A study of Mus musculus with 2 samples.

How the data were processed

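Total RNA from 2 samples of the mouse preadipocyte line 3T3-L1 was measured on 1 Affymetrix mouse array each, after biotin labelling by the manufacturer's standard protocol, per the labels. 1 sample carried an empty retroviral vector and the other a retroviral vector with Fbxl10, and both were taken at day 2 of adipocyte differentiation. The groups come from the treatment given for each sample in the labels.

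The deposited table holds 1 signal intensity per probe set and array on a linear scale, for 45101 probe sets. The authors had already scaled these intensities: after trimming the lowest and highest 2% of values, the mean signal was 100 on both arrays. The summarisation software, its settings and the scanner output behind the signals are not given in the sources used here, and no detection calls were used here. The same table holds the authors' deposited log2 ratio per probe set, to 1 decimal, which is positive where the library labelled Fbxl10 overexpression was higher. That ratio followed the log2 ratio of both signals across probe sets (Spearman correlation 0.899, over probe sets, which are not independent replicates). It was not computed from those signals alone. At 8148 bright probe sets, whose higher signal was at least 200, the difference between the ratios had an SD of 0.143. A further deposited table of values held the same signals, with 0 probe sets differing.

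Log2 differences were computed from the signals as deposited, as the library labelled Fbxl10 overexpression minus the empty vector library. 4 probe sets with a signal of 0 had no log2 difference. The plan fixed before the data were examined called a probe set detected from the authors' present calls or, without such calls, where the higher of its 2 signals reached the median of all values. The fallback applied, with a median signal of 19.4. A probe set with both signals at or above 19.4 was taken as measured on both arrays. For a probe set with 1 signal below 19.4, the difference is given as a bound, the brighter signal over the larger of 19.4 and the dimmer signal, and written "at least N-fold". The threshold is a rule of size and not a test against background.

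Gene symbols came from the deposited table and were updated through the synonyms of the NCBI RefSeq annotation of mouse assembly GRCm38.p6, which was used for names alone, so no coordinates are given. Of the probe sets, 33957 had 1 symbol, 282 had several, 10798 had none and 64 were controls. Among those with 1 symbol, 31550 matched a current RefSeq symbol or synonym and the other 2407 kept the name in the table. Probe sets with several symbols or none were left out of the gene counts. Each of the 19086 genes with a probe set was represented by its brightest detected probe set (highest mean log2 signal), which left 11326 detected genes. Probe sets of 1 gene differed in their log2 difference by an SD of 0.302, over 4615 genes with more than 1 probe set measured on both arrays. That SD was 0.359 for genes with a mean signal under 100, 0.281 between 100 and 500 and 0.198 from 500. It covers differences between probe sets on the same pair of arrays and not differences between cultures.

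With 1 array per group there was no test, no standard error and no replicate check, and the number of arrays limits the precision of every value. Genes were counted as different at a log2 difference of at least 1 in size, which is 2-fold. For 21 gene lists fixed before the data were examined, the median log2 difference of the detected members was set as a percentile among 10000 random lists of the same size, drawn from detected genes matched on mean log2 signal in 20 bins. The percentile describes these 2 libraries and is not a test of the conditions. 8 further lists were added after the data were seen.

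The genes named were chosen by a rule fixed before the data were examined. It took the target gene, the 10 highest and the 10 lowest genes measured on both arrays, the 4 largest bounds in each direction, up to 3 members at each end of every list, and a few well known members. Genes named outside the rule are said to be so, and a few genes that the rule takes are not reported here.

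The alternatives were centring the differences on the median over detected probe sets, quantile normalization, the second deposited table, detection on both arrays, no detection filter, the median over the probe sets of a gene, and raising signals below 19.4 to 19.4. After the data were seen, 4 more were added: the authors' ratio, a minimum signal of 100, centring on the hybridization spike-ins, and removal of the trend of the difference on brightness by lowess with a span of 0.3. The steps were tested on simulated data for 10968 genes, of which 200 were shifted by 2-fold or 4-fold, higher or lower. At the 2-fold threshold 98% of the genes simulated as 4-fold higher and 100% of those simulated as 4-fold lower were called. Genes simulated at 2-fold lie at the threshold itself, and the share of them called is not reported here. Of 10742 unchanged genes, 24 (0.223%) were called. The simulated noise was the SD between probe sets of 1 gene and held no difference between cultures. The 0.223% is therefore not a rate of false calls between cultures. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.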

Results

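Transcript levels were measured in 3T3-L1 cells, a mouse preadipocyte line that becomes adipocytes under a hormone cocktail. 1 sample carried an empty retroviral vector. The other carried a vector meant to overexpress Fbxl10, the older name of Kdm2b, a JmjC-domain histone demethylase and a partner of Polycomb repressive complex 1. Both samples were taken at day 2 of differentiation in medium with 10% fetal bovine serum, insulin at 1 µg/ml, dexamethasone at 0.25 µM and isobutylmethylxanthine at 0.5 mM. Each sample was hybridised to 1 array, so the differences below have no replicate check. The median signal was 17.6 in the empty vector library and 21.3 in the library labelled Fbxl10 overexpression, and 48.4% and 51.7% of 45101 probe sets reached the detection threshold of 19.4. The highest signals were 7946 and 9270. Across probe sets, the Spearman correlation between the arrays was 0.919, over probe sets that are not independent replicates.

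The target gene was not higher in the library labelled for its overexpression. Probe set 1452198_at of Fbxl10 (Kdm2b) read 431.6 in the empty vector library and 350.9 in the library labelled Fbxl10 overexpression, 1.23-fold lower (log2 difference -0.30). Probe set 1459861_s_at read 558.5 and 419.6, 1.33-fold lower (-0.41). The probe sets of 1 gene differ by an SD of 0.302 on this scale. The positions of these probe sets relative to the cloned sequence are not given in the sources used here, and a probe set outside that sequence checks nothing about the construct. As measured, both probe sets lay opposite to the label, which leaves open whether the construct was expressed, and every direction below is drawn between libraries as labelled. The related demethylase Kdm2a read 381.3 and 459.6 (log2 difference 0.27), with its detected probe sets between -0.19 and 0.83.

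The comparison between the libraries asks how Fbxl10 overexpression bears on gene expression early in adipocyte differentiation. Genes of the fat cell were much lower in the library labelled Fbxl10 overexpression. Fabp4, the adipocyte fatty acid binding protein, read 7433 in the empty vector library and 185.3 in the other, 40.1-fold lower. Pparg, the nuclear receptor at the head of the adipocyte programme, was 6.05-fold lower, from 912.2 to 150.8. Genes of mitosis were lower as well, while Igf2, which encodes a growth factor, was 17.7-fold higher (70.8 and 1250). Fibroblast and matrix genes were higher too, with 15 of 37 past 2-fold as deposited and 11 at the fewest over the alternatives tried.

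Of 11326 detected genes, 1104 (9.75%) were at least 2-fold higher and 604 (5.33%) at least 2-fold lower in the library labelled Fbxl10 overexpression by the signals as deposited, and 766 and 483 with dim signals raised to the threshold of 19.4. Counts in the lists are likewise by the signals as deposited, with the count at the threshold given where it differs. Among the 10105 genes measured on both arrays, 645 were at least 2-fold higher and 438 at least 2-fold lower. Of these, 74 were at least 4-fold higher and 72 at least 4-fold lower, and 10 and 15 passed 8-fold, so the excess of higher genes at 2-fold was not seen at the larger folds. With the genes measured on 1 array included, whose folds are over a signal below the threshold, the counts were 233 and 134 at 4-fold and 60 and 42 at 8-fold. Where genes past 2-fold had further probe sets measured on both arrays, 683 of these 711 probe sets (96.1%) lay in the same direction. Of the 711, 442 were at least 2-fold different in that direction. The balance of higher and lower genes depended on the scaling: 64.6% of the genes past 2-fold were higher with the signals as deposited, 44.2% (757 higher, 955 lower) when centred on the hybridization spike-ins and 47.2% (704 higher, 788 lower) with the trend on brightness removed. The median over detected probe sets was 0.11 above 0 on the log2 scale and the mean of the spike-ins 0.22 above 0, so small positive differences are to be read against those shifts.

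**Figure D1:**
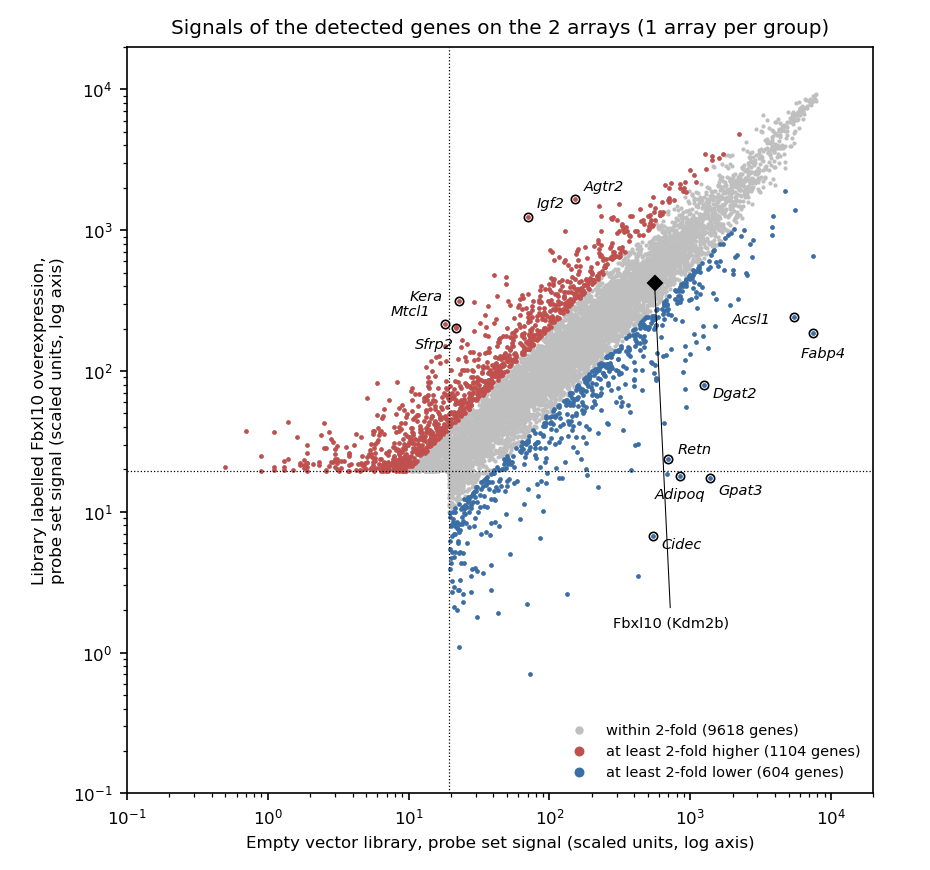
Signal of each detected gene's probe set in the empty vector library (horizontal, log axis, scaled units) and in the library labelled Fbxl10 overexpression (vertical, log axis, scaled units), with 1 point per gene and dotted lines at the detection threshold of 19.4. Fabp4 and Acsl1 lie far below the diagonal, Igf2 and Agtr2 far above it, and the black diamond marks the brighter Fbxl10 (Kdm2b) probe set at 558.5 and 419.6.

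Among genes measured on both arrays, the lowest in the library labelled Fbxl10 overexpression was Fabp4. It was followed by Retn, the hormone resistin (28.9-fold lower), Acsl1, which activates long-chain fatty acids (22.7-fold lower), and Plin4, a lipid droplet coat protein (19.2-fold lower). Dgat2, which completes triglyceride synthesis, was 15.9-fold lower (1257 and 79.0), Plaat3, a phospholipase of adipose tissue, 15.4-fold lower, and Agt, angiotensinogen, 12.4-fold lower. Map7d2 (16.8-fold lower), Ctla2a (14.1-fold lower) and the coactivator Ppargc1b (13.5-fold lower) completed the 10 lowest. Whether the probe set of Ctla2a also reads its near-identical neighbour Ctla2b was not examined, so its value is uncertain. A further 4 genes had signals under the threshold in that library at their brightest probe set, to which the bounds apply. Gpat3, a glycerol-3-phosphate acyltransferase, was at least 70.7-fold lower, Adipoq (adiponectin) at least 43.4-fold, the fatty acid transporter Cd36 at least 35.4-fold and the lipid droplet protein Cidec at least 28.2-fold. The 3 detected probe sets of Cd36 ranged from -8.30 to -2.62 on the log2 scale, so its bound does not hold for the gene as a whole.

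Highest in that library among genes measured on both arrays was Igf2. It was followed by Kera, a matrix proteoglycan (22.9 and 312.7, 13.7-fold higher), Agtr2, an angiotensin II receptor (152.4 and 1657, 10.9-fold higher), and Tmem158 (10.6-fold higher). The transcription factor Osr2 was 9.43-fold higher, the protocadherin Fat4 9.38-fold, the secreted Wnt modulator Sfrp2 9.30-fold, the chemokine Cxcl5 8.47-fold, Medag 8.05-fold and Pawr 7.85-fold. Genes under the threshold in the empty vector library included Mtcl1 (at least 11.1-fold higher), Lbh (at least 7.81-fold), the cGMP-dependent kinase Prkg1 (at least 6.57-fold) and the gelatinase Mmp9 (at least 6.45-fold), each at its brightest probe set. Their probe sets differed, between 2.44 and 3.58 on the log2 scale for Mtcl1, between 1.25 and 2.95 for Prkg1 and between 3.003 and 4.82 for Mmp9.

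**Figure D2:**
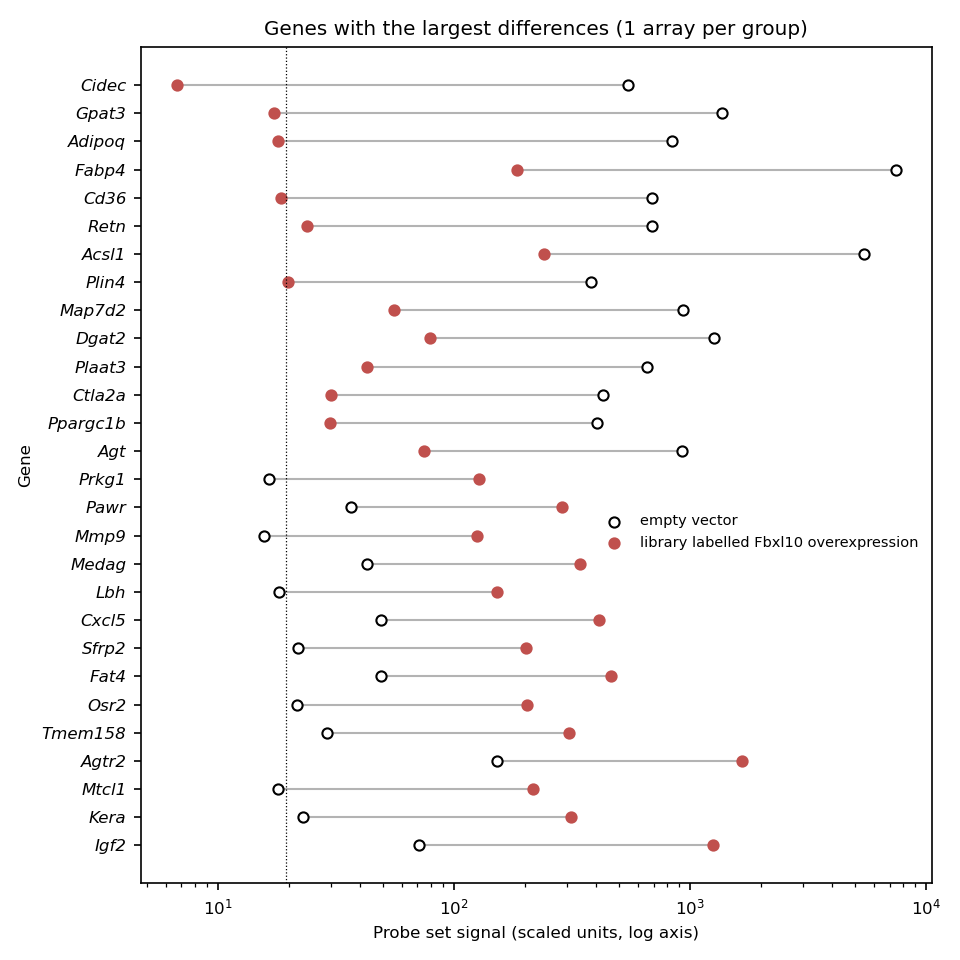
Probe set signals (horizontal, log axis, scaled units) of the genes with the largest differences, with 1 row per gene, an open circle for the empty vector library, a filled circle for the library labelled Fbxl10 overexpression and a dotted line at the detection threshold of 19.4. Fabp4 stands at 7433 and 185.3, and Igf2 at 70.8 and 1250.

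Of 29 detected adipocyte genes, 24 were at least 2-fold lower and 0 at least 2-fold higher in the library labelled Fbxl10 overexpression. Their median log2 difference was -2.53, below all 10000 random lists of the same size and brightness, and -2.34 with dim signals raised to the threshold. Cfd, the secreted protease adipsin, read 426.5 in the empty vector library and was under the threshold in the other. Lpl, the lipoprotein lipase, named here after its value was seen, was 4.01-fold lower (5591 and 1395) and the fatty acid synthase Fasn, also named afterwards, 2.06-fold lower. Acly (log2 difference -0.30) and Scd2 (-0.25) were within 2-fold, and Elovl6 was the single member above 0 (0.73).

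Of 18 adipogenic transcription factors detected, 4 were at least 2-fold lower by the signals as deposited: Pparg, its coactivator Ppargc1a (at least 2.57-fold), the lipogenic factor Srebf1 (2.78-fold) and Stat5a (2.68-fold), which was named after its value was seen. Ebf2 (2.12-fold) and Zfp467 were the 2 past 2-fold in the higher direction by the signals as deposited. Zfp467 was measured on 1 array and its bound is at least 1.93-fold, which leaves 1 with dim signals raised to the threshold. With median centring, quantile normalization or spike-in centring 0 were past 2-fold higher and 6 lower, and with the brightness trend removed 0 and 5. Under these scalings Ebf2 lay between 0.86 and 0.97 (log2). The early factors lay within 2-fold, Cebpb at -0.31 and Cebpd at 0.87 on the log2 scale. The list median was -0.45, at percentile 0.08 of random lists, and -0.16 when a signal of at least 100 was required. Cebpa had no probe set under its symbol in the table used here.

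Inhibitors of adipogenesis were higher as a list in the library labelled Fbxl10 overexpression. Of 21 detected, 5 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.37 (percentile 99.56) that was 0.15 with spike-in centring, where 3 were at least 2-fold higher. The Wnt ligand Wnt5a was 5.41-fold higher (63.6 and 343.9), the nuclear receptor Nr2f1 3.11-fold and the transcription factor Twist1 3.08-fold. Dlk1, the preadipocyte factor Pref-1, read 3825 and 4226, a log2 difference of 0.14. Foxo1 was lowest, at -0.68.

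Mitotic genes were lower nearly throughout. Of 40 detected, 20 were at least 2-fold lower (19 with dim signals raised to the threshold), 0 at least 2-fold higher and 38 below 0. The median was -0.97, below all 10000 random lists. Aurka, a mitotic kinase, was 3.32-fold lower (233.3 and 70.3), Cdca8 3.15-fold and Ccnb1, cyclin B1, 2.91-fold, while Cdk1 was at -0.87 on the log2 scale and Top2a at 0.07. The 3 detected probe sets of Cdca8 ranged from -1.66 to -0.69. Genes of DNA replication had a median of -0.44 (-0.66 with spike-in centring), also below all random lists, with 5 of 44 at least 2-fold lower as deposited (11 with spike-in centring, 3 by the authors' ratio) and 0 higher. The 5 were Rrm2, a subunit of ribonucleotide reductase (3.32-fold lower), Ccne1, cyclin E1 (3.08-fold), the helicase subunit Cdc45 (2.97-fold), Cdc6 and Tk1, the last 2 named after their values were seen. Uhrf1, which recruits the maintenance DNA methyltransferase, read 177.4 and 100.4 (-0.82).

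Cell cycle inhibitors, G1 cyclins and p53 targets went both ways. Of 25 detected, 4 were at least 2-fold higher and 3 at least 2-fold lower (5 with spike-in centring), with a median of 0.22 (percentile 97.83) that came down to 0.003 with spike-in centring. Ccnd1, cyclin D1, was 5.39-fold higher (232.0 and 1251), Plk2 4.86-fold and the CDK4/6 inhibitor Cdkn2b 3.39-fold. Gadd45b, named after its value was seen, was the remaining gene past 2-fold in that direction (2.37-fold). Gadd45g was 2.75-fold lower, the CDK inhibitor Cdkn1a 2.74-fold and Cdkn2c 2.33-fold. The 2 detected probe sets of Cdkn1a were at -1.46 and -0.71 on the log2 scale. Cdkn2a read 75.6 and 101.2 (log2 difference 0.42).

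Polycomb genes stood close to the random lists, with a median of -0.10 (percentile 12.36) and 27 of 30 detected members within 2-fold. Bcor, the corepressor of the complex that contains Kdm2b, was 2.40-fold higher (73.0 and 175.4). Pcgf5 was 2.01-fold lower, and Phf19 was under the threshold in the library labelled Fbxl10 overexpression, at least 1.20-fold lower. With dim signals raised to the threshold, 1 member was at least 2-fold higher and 1 lower, and spike-in centring put the median at -0.32. Ezh2 was at -0.34, Rnf2 at 0.21 and Pcgf1 at 0.01 on the log2 scale. For the JmjC histone demethylases, 15 detected members were all within 2-fold, with Kdm6a highest (0.59) and Jmjd6 lowest (-0.48). Their median was 0.18 (percentile 87.65) and -0.044 with spike-in centring, so its sign depended on the scaling.

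Among Hox cluster genes, which Polycomb complexes repress in many cell types, 13 were detected. Of these, 2 were at least 2-fold higher, Hoxa2 among them (2.24-fold), and 0 were at least 2-fold lower, while Hoxd4 (-0.73) and Hoxd8 (-0.64) were below 0. With quantile normalization, spike-in centring or the brightness trend removed, 0 were past 2-fold higher and 1 lower. The median of 0.05 (percentile 34.15) lay inside the random lists and turned to -0.17 at the lowest of the scalings tried.

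Fibroblast and extracellular matrix genes had the highest median of the fixed lists, 0.63 (0.41 with spike-in centring), above all 10000 random lists. Of 37 detected, 15 were at least 2-fold higher and 2 at least 2-fold lower in the library labelled Fbxl10 overexpression. Over the alternatives tried, the number at least 2-fold higher ran from 11 to 17 and the number lower from 2 to 3. The stromelysin Mmp3 was 7.17-fold higher (34.8 and 249.6), and thrombospondin Thbs1 5.63-fold. The lysyl oxidase Loxl2 was at least 2.73-fold higher. Tnc, tenascin C, was 2.20-fold lower (164.3 and 74.8).

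Several lists of growth and metabolism were lower in the library labelled Fbxl10 overexpression. Ribosome biogenesis had a median of -0.65 and mitochondrial respiration one of -0.53, both below all 10000 random lists, with 3 of 26 and 3 of 31 detected members at least 2-fold lower as deposited and 0 higher in either. With spike-in centring 9 and 6 were at least 2-fold lower, and with median centring 5 in each. Wdr12 was 2.58-fold lower, Dkc1 2.29-fold and Nolc1 2.20-fold. Idh3a, a subunit of a citric acid cycle dehydrogenase, was 5.02-fold lower (2506 and 499.6), cytochrome c (Cycs) 2.49-fold and Ogdh 2.01-fold. Cholesterol synthesis and uptake had a median of -0.60, below all random lists, with 7 of 24 at least 2-fold lower (6 with dim signals raised to the threshold, 11 with spike-in centring) and 0 higher. Hmgcs1 was 3.21-fold lower, Lss 2.61-fold and Msmo1 2.47-fold, while Tm7sf2 (0.60) was above 0. The 5 detected probe sets of Hmgcs1 ranged from -1.89 to -0.68 on the log2 scale, and the 2 of Lss from -1.38 to -0.53.

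Stress and hormone response lists were mixed. For endoplasmic reticulum and amino acid stress, 4 of 21 were at least 2-fold lower and 0 higher, with a median of -0.32 (percentile 1.16) that was -0.54 with spike-in centring. Chac1, which degrades glutathione, was 5.71-fold lower (128.5 and 22.5) and the chaperone Dnajb9 3.06-fold lower. Of 25 glucocorticoid and cAMP response genes, 6 were at least 2-fold higher, among them Fos (3.23-fold) and Sgk1 (2.86-fold), and 2 were at least 2-fold lower as deposited. These were Lcn2 (3.27-fold) and Timp4, which was under the threshold in 1 library and at least 1.85-fold lower, so 1 is left with dim signals raised to the threshold. Their median of 0.12 (percentile 81.06) was -0.10 with spike-in centring. Of 14 interferon response genes, 3 were past 2-fold in each direction around a median of 0.51 (percentile 81.94). With dim signals raised to the threshold, 1 was left in each direction and the median was 0.26, and with the brightness trend removed it was 0.098, with 1 past 2-fold higher. Isg15, close to the threshold, was at least 2.40-fold higher.

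Markers of other cell types were mostly undetected. For osteoblasts and chondrocytes, 6 of the 17 genes with a probe set were detected, 2 at least 2-fold higher and 2 at least 2-fold lower, with a median of -0.42 (percentile 4.53). With dim signals raised to the threshold, 1 was left in each direction and the median was -0.014, and with the brightness trend removed it was -0.77, with 1 past 2-fold higher. The osteoblast factor Runx2 was 3.89-fold higher (158.9 and 618.5) and Prg4, lubricin, 2.77-fold lower, while Acan (at least 1.06-fold higher) and Alpl (at least 1.08-fold lower) were each measured on 1 array. Among muscle markers 3 were detected, all within 2-fold as deposited and each measured on 1 array (median -0.74, percentile 3.55, and -0.47 with dim signals raised to the threshold). With quantile normalization or the brightness trend removed, 2 of them were past 2-fold lower, and 1 with spike-in centring. Among macrophage and leukocyte markers 4 were detected (median 0.59, percentile 70.53, 0.36 with dim signals raised to the threshold and 0.075 with the brightness trend removed), of which Cd14 was at least 3.53-fold higher. Eng was the 1 endothelial or epithelial marker detected (0.29, percentile 50.81), with a sign that depended on the scaling. Of 13 reference genes 12 were within 2-fold, with a median of 0.08 (percentile 72.79) that was -0.14 with spike-in centring. Tfrc, the transferrin receptor, was 2.15-fold lower.

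**Figure D3:**
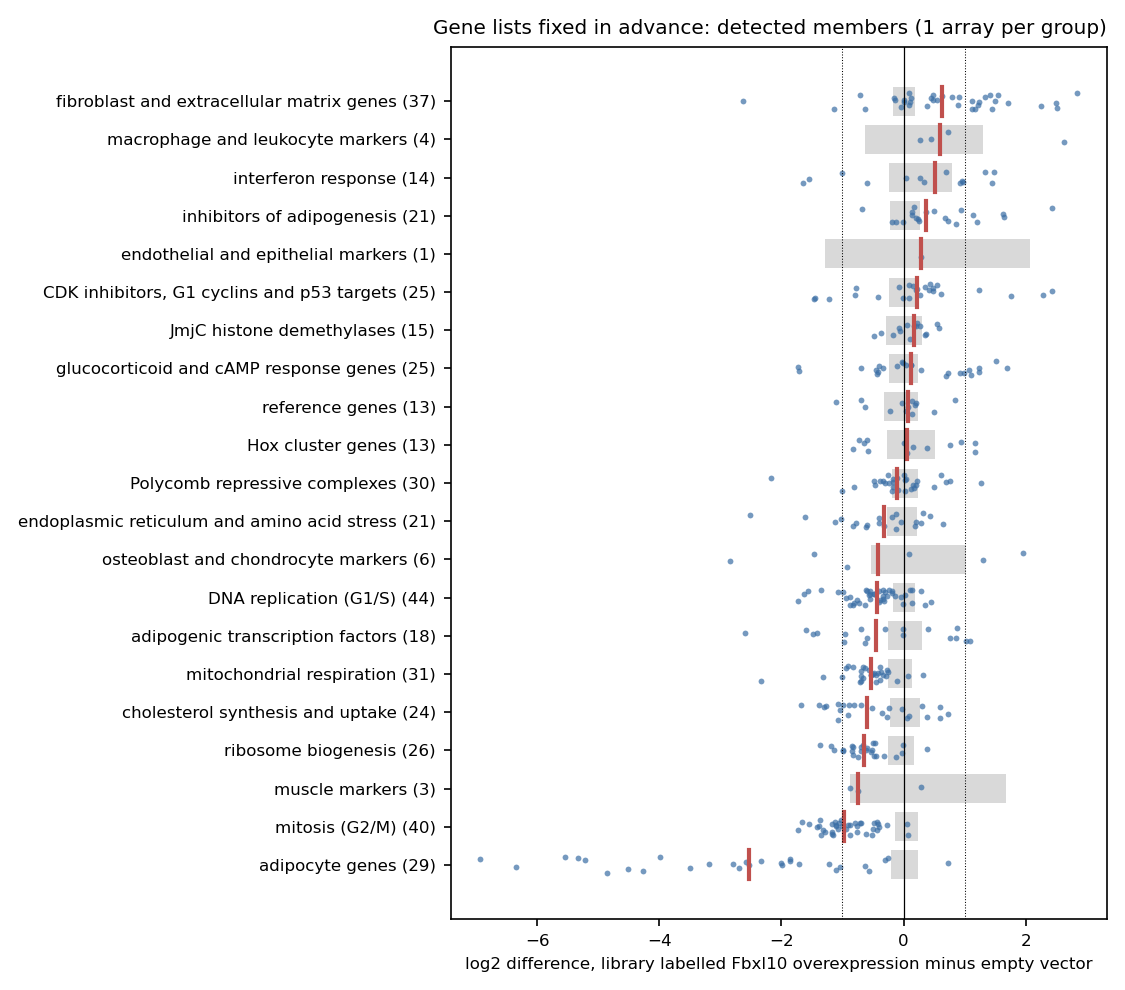
Log2 difference (horizontal, library labelled Fbxl10 overexpression minus empty vector) of every detected member of the 21 fixed lists, with 1 blue point per gene, a red bar at the list median, a grey band for the central 95% of 10000 brightness-matched random lists, dotted lines at 2-fold and the number of detected members in brackets. The median of adipocyte genes (-2.53) lies far left of its band and that of fibroblast and extracellular matrix genes (0.63) right of it; the medians of the JmjC, Hox, glucocorticoid and cAMP, endothelial and epithelial, and reference lists change sign between scalings.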

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

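All tests of explanations in this part were chosen after the results were seen. The 2 probe sets of the target gene Fbxl10 (Kdm2b) were not higher in the library labelled Fbxl10 overexpression. Over the scalings tried, the highest log2 difference of either probe set was -0.24. Median and spike-in centring could only lower both probe sets, so they could not decide whether scaling was the cause. Quantile normalization and removal of the brightness trend could have raised them and did not bring either above 0. Among detected genes their log2 differences stood at percentiles 25.78 and 19.66, ranks that scaling by 1 factor does not change. It stays open whether both probe sets lie outside the cloned sequence and so could read the cell's own transcript alone, since their positions were not used here. If they lie inside it, their mean of -0.36 would not go with an expressed construct under the labels as given. Exchanged labels cannot be told apart from correct ones either, because 0 further markers of the construct have a probe set known here. All directions in the text depend on the labels as given.

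Adipocyte genes were lower in the library labelled Fbxl10 overexpression. Scaling of the arrays, by 1 factor or by brightness, would move genes of like brightness together and is argued against as the whole cause: the list median of -2.53 differed by -2.56 (log2) from the median of brightness-matched random lists, whose central 95% ran from -0.20 to 0.24. RNA degradation in 1 library is argued against as well, since the ratio of 3′ to 5′ signals of 4 control transcripts differed by 0.10 (log2) in the median. A smaller share of differentiating cells cannot be told apart from a lower level in every cell: the 22 members measured on both arrays spread with an SD of 1.62 around no common factor (probe sets of 1 gene, 0.302), but a smaller share would give such a spread too, since members that preadipocytes also express would be lower by less. An effect of the Fbxl10 vector on differentiation was not tested apart from these, with 1 array per group.

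Several signals lay in probe sets outside the gene-level comparison. The 18 hybridization spike-in probe sets, which read RNA added in fixed amounts, were higher in the library labelled Fbxl10 overexpression by a mean of 0.22 on the log2 scale, with an SD of 0.070. The 4 control probe sets of pyruvate carboxylase, an enzyme that feeds fatty acid synthesis, had log2 differences between -2.23 and -1.91. Those of the transferrin receptor, 3 in number, lay between -1.29 and -1.11. A probe set shared by Acta2, smooth muscle actin, and an unnamed clone read 66.7 and 455.1, a log2 difference of 2.77. A total of 2877 probe sets without a symbol were measured on both arrays. In the library labelled Fbxl10 overexpression 294 of these (10.2%) were at least 2-fold higher and 71 (2.47%) at least 2-fold lower. Among genes measured on both arrays the shares were 6.38% and 4.33%. The probe sets without a symbol were counted with the signals as deposited alone, and whether their balance depends on the scaling was not tested.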

How the results depend on the processing

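Of the alternatives, 7 were fixed before the data were examined and 4 were added after. The number of genes at least 2-fold higher was 645 when detection on both arrays was required, 3278 with no filter (1993 lower), 485 with a signal of at least 100 (387 lower) and 704 with the brightness trend removed; with spike-in centring 955 were lower. The median of adipocyte genes was -2.003 with detection on both arrays, -1.996 with no filter and -2.20 with the authors' ratio. With a signal of at least 100, adipogenic transcription factors were at -0.16, Hox genes at -0.58 and cholesterol genes at -0.86. Spike-in centring moved mitosis to -1.20, DNA replication to -0.66, Polycomb genes to -0.32, matrix genes to 0.41, ribosome biogenesis to -0.87 and mitochondrial respiration to -0.76, and turned the cytosolic ribosomal proteins to -0.008; each moved by the spike-in mean. The median over probe sets put matrix genes at 0.82, and no filter put osteoblast and chondrocyte markers at 0.46. Filters act by leaving out or adding dim genes; elsewhere the cause was not tested. Of 151 named genes, 88 were at least 2-fold different. Of these, 0 changed direction and 17 came under 2-fold in at least 1 of the 11 alternatives that kept them. Detection on both arrays kept 120 of the 151, and a signal of at least 100 kept 111. Centring moved differences by 0.11 or 0.22, too little to reverse one past 2-fold. Raising dim signals to the threshold could not reverse one either, and the filters reuse the same signals. For these alternatives the 0 reversals therefore say little. Of the 151, 26 moved by more than 0.592 (log2) in at least 1 alternative. The second deposited table moved nothing. The authors' own change calls were not run, because the files used here hold none, and leaving out a replicate was not possible. No paired analysis was possible because each group has 1 sample. Signals near the threshold limit what dim genes show.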

Other observations

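The lists in this part, and the tests of them, were chosen after the data were seen. Cell guidance genes were higher in the library labelled Fbxl10 overexpression. Counts are by the signals as deposited, with the count at the threshold of 19.4 in brackets where it differs. Of 27 detected semaphorins, ephrins and Eph receptors, 10 (7) were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 difference of 0.62 (percentile 99.90 of brightness-matched random lists) that was 0.39 with the brightness trend removed. Efnb2 read 129.6 and 615.9 (4.75-fold higher), Epha4 23.1 and 95.6 (4.14-fold) and Sema5a 85.5 and 338.1 (3.95-fold). Of 9 secreted metalloproteinases of the Adamts family, 4 (3) were at least 2-fold higher, Adamts5 among them (3.03-fold), and Adamts15 was 4.36-fold lower (median 0.95, percentile 99.93). Of 22 Wnt receptors, ligands and antagonists, 8 (6) were at least 2-fold higher and 1 lower. Their median of 0.45 (percentile 95.83) was 0.13 with the brightness trend removed, where 3 were at least 2-fold lower. The receptor Fzd1 read 658.8 and 2104 (3.19-fold higher), and the coreceptor Lrp5 241.9 and 109.6 (2.21-fold lower).

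Genes of protein production and turnover parted. Of 77 mitochondrial ribosomal protein genes, 71 were below 0 (median -0.43, below all 10000 random lists) and 4 were at least 2-fold lower as deposited, Mrpl12 the furthest (3.14-fold). With median centring 7 were, and with spike-in centring 13, where that median was -0.65, as was that of the proteasome subunits. Of 36 proteasome subunits 33 were below 0 (median -0.43, below all 10000 random lists), with Psma5 lowest (2296 and 916.5). Of 78 cytosolic ribosomal protein genes 76 were above 0, at a median of 0.21, above all 10000 random lists. That median was -0.008 with spike-in centring, so its sign depends on the scaling, while scaling by 1 factor leaves the rank unchanged. Zinc finger (Zfp) genes had a median of 0.24 over 224 detected (percentile 99.49), with 18 (14) at least 2-fold higher and 2 (1) lower. It came down to 0.069 with the brightness trend removed (7 at least 2-fold higher, 6 lower) and to 0.014 with spike-in centring (9 higher, 6 lower). Zfp521, which restrains adipocyte commitment, read 144.1 and 463.6 (3.22-fold higher).

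Imprinted genes may be higher as a class in the library labelled Fbxl10 overexpression, a hypothesis raised by Igf2 and Plagl1, which were left out of the list because their values had been seen. Plagl1, a regulator of other imprinted genes, read 105.2 and 698.3 (6.64-fold higher). Of 20 other imprinted genes detected, 5 were at least 2-fold higher and 0 at least 2-fold lower as deposited (1 lower with each of the other scalings), with a median of 0.49, among them Slc38a4 (4.16-fold), Peg3 (3.69-fold) and H19 (3.17-fold). Dimmer probe sets reading higher in this library is argued against as the whole cause by the percentile of 99.82 among brightness-matched random lists. Scaling by 1 factor or by brightness would move those random lists alike, so the same percentile argues against it as the whole cause. The lowest median over the scalings, 0.27, came from spike-in centring and decides nothing. Centring by 0.11 or 0.22 could not bring 0.49 to 0. With 1 array per group, a difference between cultures that is unrelated to the vector stays open.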
